A study of Mus musculus with 8 samples.

How the data were processed

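RNA of 8 samples of female mouse CD8+ T cells was measured on Clariom S Mouse arrays, with 1 array per sample. The series' design text gives naive cells, stimulated in vitro and kept 48 h with an agonist of PPARα, PPARβ or PPARγ. The sample labels give the treatment, with DMSO for the fourth group, and day 2 for every sample. Each of the 4 groups held 2 arrays. The sample titles carry 2 prefixes, each shared by 1 array of every group. The 4 arrays of 1 prefix are called a culture set here, but the labels do not say whether a prefix marks a day, a pool of cells or an animal. The compounds and their doses were not given in the sources used here.

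Per the labels, biotin-labelled single-stranded DNA was prepared from 100 ng of total RNA with the GeneChip WT PLUS kit. The deposited values were log2 RMA expression values from Expression Console, per the labels' description and the submitters' processing notes, and no version of either was given. RMA corrects the background, makes the distributions of the arrays alike and summarises the probes of each transcript cluster in 1 step, so that a change shared by most transcripts is removed. The description calls the analysis gene-level for 1 sample and exon-level for the other 7, but all 8 columns held the same 22206 transcript clusters, 22197 of them with 10 probes. Per the file headers, the annotation is release na36 on mouse genome build mm10, and all coordinates are those of that annotation. A linear intensity column per array was also deposited, and log2 of it equalled the log2 column of the same array to 1.5e-06, so it was not tested. The log2 values of the deposited workbook and of the value matrix differed by at most 5.0e-07. Array medians lay between 5.64 and 5.72 and array maxima between 19.01 and 19.16. The scaling behind maxima of that height was not given in the sources used here, and fold changes assume that the values are plain log2 units. The number of arrays, not a read depth, limits the precision of array values.

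Of the 22206 clusters, 21371 name 1 gene, 832 name several genes and 3 name none. For the clusters that name 1 gene, 20395 were matched by entrez ID to a RefSeq gene table of assembly GRCm38.p6, and 899 symbols were updated through it. Where a gene had several clusters, the cluster with the highest mean over the 8 arrays was used, which left 21160 genes. Genes with a mean log2 value of at least 4.888, the 40th percentile over these genes, were tested, 12713 in all. Clusters that name several genes were left out of the main tests, and those among them above the same mean were tested apart. The gene of PPARβ, Ppard, lies in such a cluster, shared with 1810013A23Rik, so no change of its own is given.

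The 4 group means were fitted over all 8 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes; 4 residual and 3.756 prior degrees of freedom). All 6 pairs of groups were compared, each two-sided, with Benjamini-Hochberg adjustment over the 12713 genes and a threshold of 0.05. Adjusted p-values in the text come from this fit unless a block is named. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared the tables and the plots. The labels do not say that the arrays of a group came from separate animals or cultures, so p-values measure only the spread between these arrays, which may be partly technical.

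The culture set entered a second fit as a replicate block (3 residual and 4.266 prior degrees of freedom). The pairing comes from the shared title prefix and was checked in the data. Over the 12713 genes, the differences between the sets of any 2 groups correlated at 0.495 to 0.550 in all 6 pairs of groups, so the set was taken to pair the arrays. Fold changes are equal with and without the block because each set holds 1 array of every group. Without the block the difference between sets stays in the spread and raises the p-values of genes that differ between the sets.

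Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists. There were 33 lists, 25 of pathways or processes and 8 of cell type markers, with 729 genes. Of these genes, 696 had a cluster of their own, 30 shared a cluster, 3 had none and 589 were tested. The list of erythroid markers had fewer than 3 tested members and was left out, which left 32. Within each list, limma's p-values were also adjusted over the list alone. Camera with an estimated correlation and fry, which does not compare a list with other genes, were alternatives.

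Genes were named by a fixed rule. It takes up to 8 genes per direction with an adjusted p under 0.05 in either fit, filled to 4 by the largest mean changes of at least 0.3 in both culture sets. It adds up to 4 members of every list past its threshold, the 3 receptor genes, and Pdk4, Cpt1a, Angptl4, Plin2, Ifng, Gzmb and Cd8a. Predicted genes and gene families of receptor segments, olfactory receptors and small RNAs were counted but not named. Genes outside this rule are said to have been chosen after their values were seen. The groups, tests, gene lists, naming rule and the other settings, apart from those said below to be added later, were fixed before the data were examined.

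The tests were tried on simulated data for the PPARβ agonist against DMSO. Over 10 runs with 200 of 12713 genes changed, the fit without the block called 0 percent of genes changed 1.5-fold, 13.6 percent at 2-fold, 89.0 percent at 4-fold and 96.8 percent at 8-fold. With the block these shares were 20.2, 85.0, 100 and 100 percent. These runs used limma's moderated variances, and moderation lowers the mean variance, so the shares may run high. Unchanged genes were called at a mean of 0.2 per run without the block and 10.7 per run with it. A shift of 0.4 in a list was called in 10 of 10 runs by camera in both fits, and 0 unchanged lists were called. Genes were simulated as independent, so these runs cannot show how often camera calls an unchanged list whose genes correlate. In the real arrays the estimated correlation was 0.515 for mitochondrial fatty acid oxidation and 0.178 for the interferon response list.

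The results were also computed with the block, no filter on dim genes, a filter at the 60th percentile (a mean of 7.113, 8519 genes), the mean of a gene's clusters, arrays centred on their medians, quantile normalization of the tested genes and the other deposited table. An intensity trend with robust variances, looser and stricter thresholds, only the 4 arrays compared, the other list tests and leaving out each array in turn were used too. When 1 array is left out, limma pools the spread, so the lone array of a group is assumed to vary like the other groups. Clusters naming several genes, the block combined with the other list tests and the comparison of the culture sets were added after the data were seen.

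The 3 comparisons with DMSO share the DMSO arrays. Chance covariance of their log2 changes was simulated 100 times from unchanged, independent genes with the residual variances of the fit. This simulation was run with limma's moderated variances before, and was changed after its result was seen, because moderation lowers the mean variance; both values are given.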

Results

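Transcript levels were measured on 8 arrays of mouse CD8+ T cells, the cytotoxic arm of the T cell response, after 48 h of culture with DMSO or with an agonist of PPARα, PPARβ or PPARγ. These 3 receptors are fatty acid-binding nuclear receptors that switch on genes of lipid metabolism. Each group held 2 arrays, 1 from each of 2 culture sets, and 12713 genes were tested. Values are log2 RMA values, means are given ± SD with n = 2 arrays, and coordinates are on build mm10.

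The samples carried the transcripts of activated cytotoxic T cells in every group. Cd8a, a chain of the CD8 co-receptor, averaged 16.70 ± 0.01 with DMSO and 16.56, 16.55 and 16.65 with the PPARα, PPARβ and PPARγ agonists. Gzmb, which encodes the killing protease granzyme B, averaged 14.66, 14.53, 14.93 and 14.64 in the same order. Ifng, the gene of interferon gamma, differed mainly between the culture sets, at 11.54 in set 1 and 7.42 in set 2 with DMSO, 10.85 and 8.18 with the PPARα agonist, 12.12 and 8.71 with the PPARβ agonist, and 12.80 and 8.08 with the PPARγ agonist. Ppara (chromosome 15, 85734983 to 85806851) lay near the lower limit of the tested genes, at 5.10, 5.17, 4.87 and 4.89. Pparg (chromosome 6, 115361221 to 115490401) lay below it, at 3.72, 3.72, 3.82 and 3.74. The cluster shared by Ppard and 1810013A23Rik averaged 9.61, 9.90, 9.37 and 9.65.

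Culture set explained 45.4 percent of the variance of the tested genes and treatment group 28.7 percent. Group means of unchanged treatments would also take a share of the variance, so 28.7 percent does not measure an effect of treatment. Arrays of 1 set correlated at 0.994 to 0.996 across genes, arrays of different sets at 0.988 to 0.992, and the 2 arrays of a treatment at 0.989 to 0.991. The median SD between the 2 arrays of a group was 0.233, and the median residual SD with culture set as a block was 0.163.

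**Figure D1:**
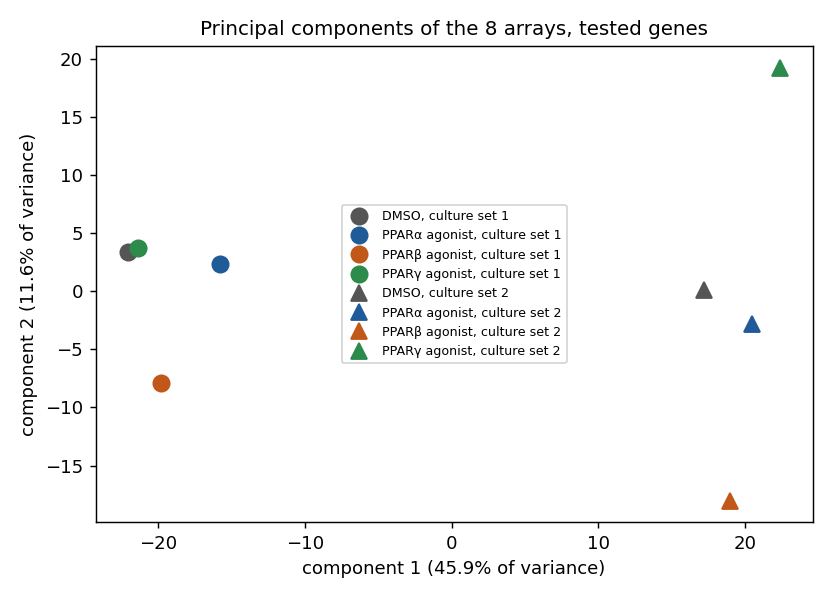
Principal components of the 8 arrays over the tested genes, with component 1 (45.9% of variance) across and component 2 (11.6% of variance) up; each point is 1 array, colours are treatments, circles are culture set 1 and triangles culture set 2. Component 1 separates the culture sets, and the PPARβ arrays have the lowest component 2 value within each set.

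The question of the PPARβ agonist against DMSO is which transcripts this agonist moves in CD8+ T cells. Rhob, which encodes a small GTPase of the actin cytoskeleton and endosomes, rose 6.42-fold, from 5.21 ± 0.04 to 7.89 ± 0.14 (log2 change 2.68, SE 0.203, limma adjusted p = 0.0173), by 2.81 in set 1 and 2.55 in set 2, from a DMSO level near the lower limit of the tested genes. Plin2, which encodes a coat protein of lipid droplets and is a known PPAR target, stood at 6.64 ± 0.97 with DMSO and 10.38 ± 1.21 with the agonist. Its change of 3.74 (13.35-fold) passed with culture set as a block (SE 0.253, adjusted p = 0.0071) and not without it (adjusted p = 0.9999), with 3.57 and 3.91 in the sets. Klf11, a Krüppel-like transcription factor, stood at 6.03 ± 0.14 and 8.41 ± 0.64. Its change of 2.38 (5.19-fold) also passed with the block (SE 0.211, adjusted p = 0.0307) and not without it (adjusted p = 0.431).

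limma called 1 of 12713 genes higher and 0 lower without the block, and 3 higher and 0 lower with it. At an unadjusted p under 0.05 there were 299 genes without the block (143 higher, 156 lower) and 780 with it, where 636 were to be reached by chance. The fit without the block leaves the difference between culture sets in the spread, so its p-values run high. Rhob lies at chromosome 12, 8497758 to 8499996, Klf11 at chromosome 12, 24651371 to 24662782, and Plin2 at chromosome 4, 86648386 to 86670060. The Rhob call was lost without DMSO set 1 (adjusted p = 0.347), DMSO set 2 (0.302), PPARβ set 1 (0.152), PPARβ set 2 (0.186) or either PPARγ array (0.0911), with the change between 2.58 and 2.78. With the block, an intensity trend and robust variances together 10 genes passed, and with the filter at the 60th percentile, which leaves Rhob out, 0 did.

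**Figure D2:**
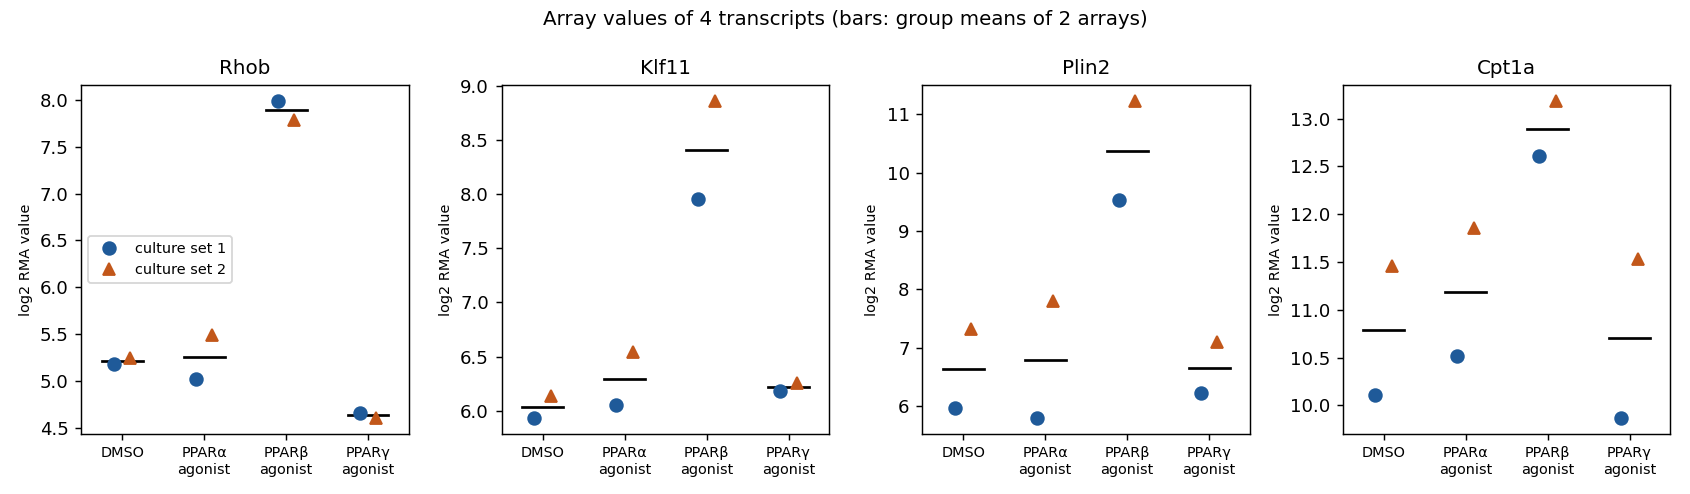
Log2 RMA values (vertical axis) of Rhob, Klf11, Plin2 and Cpt1a on the 8 arrays by treatment (horizontal axis); circles are culture set 1, triangles culture set 2 and bars the group means of 2 arrays. With the PPARβ agonist the means were 7.89, 8.41, 10.38 and 12.90, against 5.21, 6.03, 6.64 and 10.79 with DMSO; vertical axes do not start at 0.

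Mitochondrial fatty acid oxidation, the pathway that burns fatty acids, rose as a list with the PPARβ agonist. Its 18 tested members averaged a change of 0.42 (0.48 in set 1, 0.36 in set 2; median 0.17), and 16 lay above 0 (camera adjusted p = 5.46e-05). The list did not pass with an estimated correlation (adjusted p = 0.885 with an estimated correlation). Its largest values were those of Cpt1a, the carnitine transferase that admits long-chain fatty acids to mitochondria, at 2.11, Acadvl, a dehydrogenase of very long chains, at 1.23, Slc25a20, the carnitine carrier, at 1.02, and Etfdh, which passes the electrons on, at 0.78. Over all genes tested 0 members passed limma's threshold in either fit, with 3 at an unadjusted p under 0.05 without the block and 7 with it. With p adjusted over the list alone, 0 members passed without the block and 5 with it, namely these 4 and the thiolase gene Acaa2 at 0.65, which was named after the values were seen. The other 13 members averaged 0.14 and ranged from -0.20 to 0.42. The list call was lost without DMSO set 1 (mean 0.19, adjusted p = 0.218) or PPARβ set 2 (mean 0.25, adjusted p = 0.168), and without DMSO set 2 the mean was 0.655.

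The list of type I and II interferon response genes, which antiviral and inflammatory signals induce, also rose with the PPARβ agonist, by a mean of 0.20 over 32 members (0.18 and 0.22 in the sets), with 25 above 0 (camera adjusted p = 0.0202; adjusted p = 0.885 with an estimated correlation). Examples were Ifi44 at 0.94, Iigp1 at 0.65, Usp18 at 0.52 and Gbp2 at 0.47, and 0 members passed limma's threshold over all genes tested or adjusted over the list alone, with 0 at an unadjusted p under 0.05 without the block and 4 with it. Without PPARβ set 1 the mean was -0.05 and without DMSO set 2 it was -0.06, and the call was lost each time. Leaving out 1 array unbalances the culture sets, whose DMSO arrays stood at 10.72 in set 1 and 10.20 in set 2 for this list. These turned means thus hold the set difference, while the change within each set was above 0. The mean was 0.458 without DMSO set 1 and 0.442 without PPARβ set 2.

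The remaining 30 lists did not pass in this comparison (smallest adjusted p = 0.342, means from -0.21 to 0.31). PPAR lipid-handling targets had a mean of 0.31 and a median of -0.01 over 17 members (adjusted p = 0.342). Adjusted over the list alone, Plin2 and Hilpda, which encodes an inhibitor of lipid breakdown at the droplet, passed in both fits. Hilpda, like H2-Ab1 below, was chosen after the values were seen, and it stood at 1.33 with an adjusted p over all genes of 0.9999 without the block and 0.0760 with it. Also chosen after the values were seen, the cytotoxic regulator gene Tbx21 at 0.85 and the interleukin 12 receptor gene Il12rb2 at 0.60 passed adjusted over the list alone of CD8 effector molecules with the block, and Acbd4, Acsl1 and Slc27a1 passed below 0 in that of fatty acid uptake. Angptl4, another PPAR target, stood at 0.48 (adjusted p = 0.9999). Pdk4 (3.44 against 3.57) lay below the tested range. Ifng, Gzmb, Cd8a and Ppara stood at 0.93, 0.27, -0.15 and -0.23 (adjusted p = 0.9999 each). Among genes that fell by at least 0.3 in both sets, the largest values were those of Pou4f1 at -1.11, Caskin2 at -1.11, Slc41a2 at -0.99 and Fah at -0.93 (adjusted p = 0.9999 each). Of the markers of other cell types, H2-Ab1, a class II antigen presentation gene of B cells, stood at 1.05 (1.07 and 1.02 in the sets; adjusted p = 0.9999 over all genes), and it passed adjusted over the list alone with the block, while the 6 tested B cell markers had a median of -0.06.

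**Figure D3:**
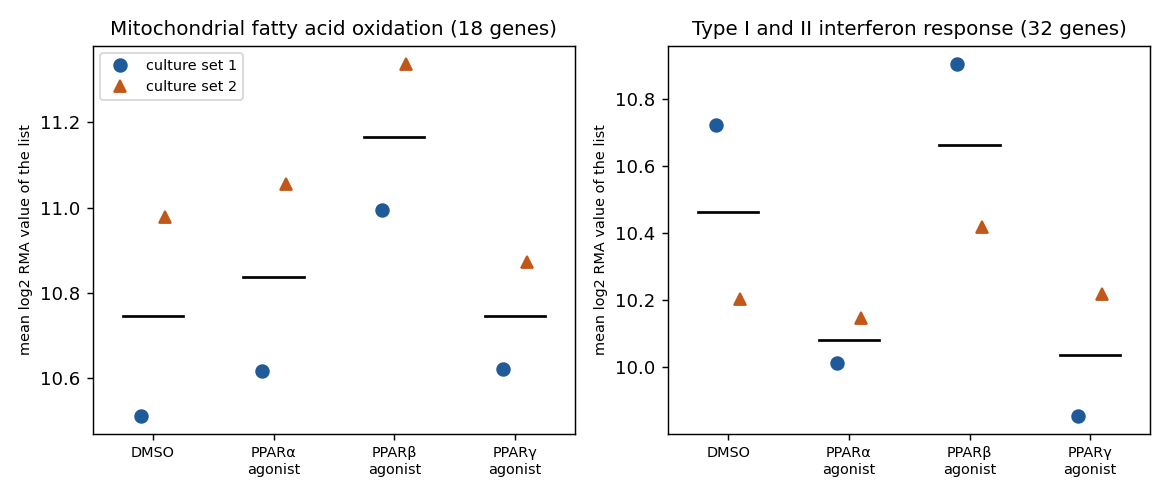
Mean log2 RMA value of the 18 tested mitochondrial fatty acid oxidation genes (left) and the 32 tested interferon response genes (right) on each array (vertical axis) by treatment (horizontal axis); circles are culture set 1, triangles culture set 2 and bars group means of 2 arrays. The fatty acid oxidation mean was highest with the PPARβ agonist in both sets (10.99 and 11.34), and the interferon mean was also highest there (10.91 and 10.42); vertical axes do not start at 0.

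For the PPARα agonist against DMSO, the interferon response list fell by 0.38 on average over its 32 members, with 26 below 0 (camera adjusted p = 0.0039; adjusted p = 0.957 with an estimated correlation). The mean was -0.71 in set 1 and -0.06 in set 2, and the median was -0.18. Its largest values were those of Oasl2 at -1.38 (-2.34 in set 1, -0.41 in set 2), an oligoadenylate synthetase-like protein, Mx1 at -1.16, an antiviral GTPase, Ifit3 at -1.14, and Usp18 at -1.06, a protease that removes the ubiquitin-like protein ISG15. Their SEs were 0.932, 0.898, 0.877 and 0.638, and limma passed 0 members over all genes tested and 0 adjusted over the list alone, with 1 at an unadjusted p under 0.05 without the block and 2 with it. The list call was lost without DMSO set 1 (mean -0.12, adjusted p = 0.535), without PPARα set 1 (mean -0.32, adjusted p = 0.252) and with the filter at the 60th percentile (adjusted p = 0.287), and without DMSO set 2 the mean was -0.642.

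limma called 0 of 12713 genes with the PPARα agonist, with 225 genes at an unadjusted p under 0.05, where 636 were to be reached by chance. With the block, which takes the set difference out of the spread, it called 0 genes, with 617 unadjusted. Among genes that rose by at least 0.3 in both sets, the largest values were those of Vmn1r189 at 1.34 and Vmn2r25 at 1.22, both vomeronasal receptor genes. With them stood Ctsm at 1.32, a placental cathepsin, and Pygl at 1.02, a glycogen phosphorylase (adjusted p = 0.9999 for all of these). Among genes that fell by at least 0.3 in both sets, Oas3 at -0.84, Ppcs at -0.83 and Pcsk1 at -0.83 followed Oasl2 (adjusted p = 0.9999 each). Cpt1a stood at 0.40, Angptl4 at 0.28, Plin2 at 0.15, Ifng at 0.04, Gzmb at -0.13, Cd8a at -0.14 and Ppara at 0.07, each with an adjusted p of 0.9999. Pdk4 (3.46 against 3.57) lay below the tested range. Camera passed 1 of 32 lists, and the other 31 had means from -0.17 to 0.19 (smallest adjusted p = 0.366). Mitochondrial fatty acid oxidation was among these, at a mean of 0.09. In lists that did not pass, Acsl1 and Lif, chosen after the values were seen, passed below 0 adjusted over the list alone with the block.

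The PPARγ agonist was compared with DMSO in the same way, and the interferon response list fell by 0.43 on average, with 30 of 32 members below 0 (camera adjusted p = 5.66e-05; adjusted p = 0.890 with an estimated correlation). The mean was -0.87 in set 1 and 0.02 in set 2. Isg15, a ubiquitin-like interferon-induced protein, stood at -1.30 (-2.24 in set 1, -0.36 in set 2), Ifit3 at -1.08, Rtp4 at -1.01 and Mx1 at -0.999. limma passed 0 members over all genes tested and 0 adjusted over the list alone, with 2 at an unadjusted p under 0.05 without the block and 5 with it. The list call was lost without DMSO set 1 (mean -0.17, adjusted p = 0.155) and without PPARγ set 1 (mean -0.24, adjusted p = 0.640), and without DMSO set 2 the mean was -0.685.

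limma called 0 of 12713 genes with the PPARγ agonist, with 280 genes at an unadjusted p under 0.05, where 636 were to be reached by chance. With the block, which takes the set difference out of the spread, it called 0 genes, with 746 unadjusted. With the block, an intensity trend and robust variances together, 2 predicted genes passed. Among genes that rose by at least 0.3 in both sets, the largest values were those of Gpr52 at 1.61, an orphan receptor gene, Phxr4 at 1.49, Tbrg3 at 1.30 and Insyn2b at 1.05 (adjusted p = 1 each). Among genes that fell by at least 0.3 in both sets these were Ifit3b at -1.39, Isg15, Ccrl2 at -1.12, a chemokine receptor-like gene, and Sgk1 at -1.03, a serum- and glucocorticoid-regulated kinase (adjusted p = 1 each). Ifng stood at 0.96, Angptl4 at 0.17, Plin2 at 0.01, Gzmb at -0.02, Cd8a at -0.05, Cpt1a at -0.09 and Ppara at -0.21, each with an adjusted p of 1. Pdk4 (3.81 against 3.57) lay below the tested range. Camera passed 1 of 32 lists, and the other 31 had means from -0.22 to 0.13 (smallest adjusted p = 0.492). In the list of neutrophil and mast cell markers, Kit, a stem cell factor receptor gene chosen after the values were seen, stood at -0.85 (-0.76 and -0.95 in the sets; adjusted p = 1 over all genes) and passed adjusted over the list alone in both fits, while the list's median was 0.06.

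The agonists were then compared with each other, which tests their differences directly. Rhob was 6.22-fold higher with the PPARβ than with the PPARα agonist (7.89 ± 0.14 against 5.26 ± 0.33, log2 difference 2.64, SE 0.203, limma adjusted p = 0.0196). Plin2 differed by 3.59 (SE 0.253 with the block), which passed with the block (adjusted p = 0.0094) and not without it (adjusted p = 0.9999). limma called 1 gene higher and 0 lower without the block and 2 higher and 0 lower with it, with 295 and 750 genes at an unadjusted p under 0.05. The Rhob call was lost whichever array was left out, at an adjusted p of 0.0595 without PPARα set 2, 0.192 without PPARα set 1, 0.211 and 0.208 without PPARβ set 1 and set 2, 0.0969 without either DMSO array and 0.102 without either PPARγ array, with the difference between 2.40 and 2.87.

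The interferon response list was higher with the PPARβ than with the PPARα agonist by 0.58 on average, with 30 of 32 members above 0 (0.89 in set 1 and 0.27 in set 2; camera adjusted p = 6.07e-10; adjusted p = 0.629 with an estimated correlation). With 1 array left out the mean ranged from 0.337, without PPARβ set 1, to 0.824. Ifi44 differed by 1.65, Ifit3 by 1.58, Usp18 by 1.58 and Oasl2 by 1.45. limma passed 0 members over all genes tested in either fit, with 3 at an unadjusted p under 0.05 without the block and 12 with it, and adjusted over the list alone 0 passed without the block and 1 with it, the chemokine gene Cxcl10 at 1.02, named after the values were seen. Mitochondrial fatty acid oxidation was higher by 0.33, with 13 of 18 members above 0 (camera adjusted p = 0.0145; adjusted p = 0.997 with an estimated correlation). Cpt1a differed by 1.71, Acadvl by 1.19, Slc25a20 by 0.97 and Etfdh by 0.75, and adjusted over the list alone 0 members passed without the block and 6 with it, with 3 and 6 at an unadjusted p under 0.05. This call was lost without PPARα set 1 (mean 0.11, adjusted p = 0.732) and without PPARβ set 2 (mean 0.16, adjusted p = 0.767), and the mean was 0.549 without PPARα set 2 and 0.502 without PPARβ set 1.

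Fatty acid synthesis was higher with the PPARβ than with the PPARα agonist by 0.20, with 12 of 14 members above 0 (camera adjusted p = 0.0145; adjusted p = 0.629 with an estimated correlation). Fads2 and Fads1, which desaturate fatty acids, differed by 0.47 and 0.32, Scd1, another desaturase, by 0.34 and Acaca, the acetyl-CoA carboxylase, by 0.32. limma passed 0 members over all genes tested and 0 adjusted over the list alone, with 0 at an unadjusted p under 0.05 without the block and 2 with it. This call was lost without PPARβ set 1 (mean 0.15, adjusted p = 0.138) and without PPARα set 2 (mean 0.13, adjusted p = 0.262). Camera passed 3 of 32 lists without the block and 8 with it. The 5 added with the block were activation and costimulation (adjusted p = 3.90e-04), cholesterol synthesis (0.0133), the ATF4 stress response (0.0327), CD8 effector molecules (0.0352) and PPAR lipid-handling targets (0.0406). With the block these 5 had an adjusted p = 0.620 with an estimated correlation, or 0.890 for CD8 effector molecules. Ifng differed by 0.90, Gzmb by 0.40, Angptl4 by 0.20, Cd8a by -0.01 and Ppara by -0.29 (adjusted p = 0.9999 each).

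Rhob was lower with the PPARγ than with the PPARβ agonist (4.63 ± 0.04 against 7.89 ± 0.14, log2 difference -3.26, SE 0.203, limma adjusted p = 0.0040). The PPARγ mean lay under 4.888, the mean over all arrays that a tested gene had to reach, so the difference is taken from a dim level and no fold is given. The call was lost without PPARβ set 1 (adjusted p = 0.0795), PPARβ set 2 (0.0527) or PPARγ set 2 (0.101). Plin2 differed by -3.73 (13.23-fold lower), which passed with the block (adjusted p = 0.0072) and not without it (adjusted p = 1). limma called 0 genes higher and 1 lower without the block and 0 higher and 2 lower with it, with 336 and 898 genes at an unadjusted p under 0.05. Without PPARγ set 1 it called 2 genes.

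The interferon response list was lower with the PPARγ than with the PPARβ agonist by a mean difference of -0.62, with 32 of 32 members below 0 (-1.05 in set 1 and -0.20 in set 2; camera adjusted p = 3.12e-12; adjusted p = 0.653 with an estimated correlation). With 1 array left out the mean ranged from -0.868 to -0.381, the latter without PPARβ set 1. Ifi44 differed by -1.77, Ifit3 by -1.52, Usp18 by -1.47 and Rtp4 by -1.38. limma passed 0 members over all genes tested in either fit, with 4 at an unadjusted p under 0.05 without the block and 16 with it, and adjusted over the list alone 0 passed without the block and 7 with it. Mitochondrial fatty acid oxidation was lower by a mean difference of -0.42, with 14 of 18 members below 0 (camera adjusted p = 6.34e-04; adjusted p = 0.728 with an estimated correlation). Cpt1a differed by -2.20, Slc25a20 by -1.40, Acadvl by -1.15 and Etfdh by -0.78, and adjusted over the list alone 0 members passed without the block and 6 with it, with 3 and 6 at an unadjusted p under 0.05. This call was lost without PPARγ set 1 (mean -0.30, adjusted p = 0.0959) and without PPARβ set 2 (mean -0.25, adjusted p = 0.288).

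Cholesterol synthesis was lower with the PPARγ than with the PPARβ agonist by a mean difference of -0.17, with 20 of 23 members below 0 (camera adjusted p = 0.0403; adjusted p = 0.783 with an estimated correlation). Pmvk, a kinase of the pathway, differed by -0.41 and Cyp51, a demethylase, by -0.32, and limma passed 0 members over all genes tested and 0 adjusted over the list alone, with 0 at an unadjusted p under 0.05 in either fit. The mean turned to 0.06 without PPARβ set 1 and to 0.04 without PPARγ set 2, and the call was also lost with no filter (adjusted p = 0.0792). Leaving out 1 array unbalances the culture sets, which differed by 0.405 in this list. Within set 1 the list mean was 12.02 with the PPARγ and 12.22 with the PPARβ agonist, and within set 2 it was 11.60 and 11.75. The mean was -0.410 without PPARβ set 2 and -0.385 without PPARγ set 1.

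Markers of CD4 T cells, the helper arm of the T cell response, were higher with the PPARγ than with the PPARβ agonist by 0.34, with 5 of 6 members above 0 (camera adjusted p = 0.0423; adjusted p = 0.653 with an estimated correlation). Cd4 differed by 0.71, Zbtb7b, a regulator of the CD4 lineage, by 0.59, Trat1 by 0.37 and Ikzf2 by 0.29. limma passed 0 members over all genes tested, with 1 at an unadjusted p under 0.05 without the block and 2 with it, and adjusted over the list alone only Zbtb7b passed, with the block. The call was lost without PPARβ set 2 (mean 0.16, adjusted p = 0.462), PPARγ set 1 (0.32, 0.0750) or PPARγ set 2 (0.35, 0.264), with no filter (adjusted p = 0.0792), with the filter at the 60th percentile (0.133) and with an intensity trend (0.0522), and without PPARβ set 1 the mean was 0.519. Camera passed 4 of 32 lists without the block and 7 with it, where glycolysis (adjusted p = 0.0088), PPAR lipid-handling targets (0.0234) and CD8 effector molecules (0.0234) were added. With the block these 3 had an adjusted p = 0.568, 0.568 and 0.653 with an estimated correlation. Ifng differed by 0.02, Gzmb by -0.29, Angptl4 by -0.30, Cd8a by 0.09 and Ppara by 0.02 (adjusted p = 1 each).

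Between the PPARγ and PPARα agonists limma called 0 of 12713 genes without the block, with 258 at an unadjusted p under 0.05, and 0 with the block, with 727. Camera passed 0 of 32 lists (smallest adjusted p = 0.363, means from -0.20 to 0.20), 0 with an estimated correlation and 0 with fry. The interferon response list, which passed against DMSO with both agonists, differed between them by -0.04. Ifng differed by 0.92, Gzmb by 0.11, Cd8a by 0.08, Angptl4 by -0.10, Plin2 by -0.14, Ppara by -0.28 and Cpt1a by -0.49 (adjusted p = 0.9999 each). The 95% interval of the Plin2 difference ran from -1.99 to 1.71 without the block and from -0.735 to 0.454 with it, and that of Cpt1a from -2.06 to 1.08 and from -1.06 to 0.088.

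Over the 12713 genes, the log2 changes of the 3 agonists against DMSO correlated at 0.458 (PPARα and PPARβ), 0.488 (PPARα and PPARγ) and 0.425 (PPARβ and PPARγ), where unchanged groups against the same DMSO arrays gave 0.501, 0.500 and 0.499 in simulation. The covariances were 0.0221, 0.0235 and 0.0220, against 0.0235, 0.0234 and 0.0234 simulated, so that the differences were -0.0013, 0.0001 and -0.0014. With limma's moderated variances the simulated value was 0.0176 in each pair. With 2 DMSO arrays the controls could not be split into sets of at least 2 arrays, so part of any excess may come from the shared controls. Across culture sets, where no DMSO array is shared, the covariances were 0.0016, 0.0030 and 0.0011. The changes of 1 agonist in set 1 and in set 2 correlated at 0.056 (PPARα), 0.062 (PPARβ) and 0.035 (PPARγ) across genes, which are not independent replicates.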

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

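All tests of explanations in this part were chosen only after the results were seen. Each result named in the next sentence drew attention because a test of the difference between agonists passed. Between the PPARβ and PPARα agonists these were Rhob (2.64), interferon response (0.58), mitochondrial fatty acid oxidation (0.33) and fatty acid synthesis (0.20), and between the PPARγ and PPARβ agonists Rhob (-3.26), interferon response (-0.62), mitochondrial fatty acid oxidation (-0.42), cholesterol synthesis (-0.17) and CD4 T cell markers (0.34). Other results drew attention because the culture sets moved in opposite directions, and those differences between sets were not tested. With the PPARα agonist against DMSO these were, in set 1 and set 2, Gzmb (-0.343 and 0.083), Ifng (-0.692 and 0.763) and Plin2 (-0.163 and 0.469). With the PPARγ agonist they were the interferon response list (-0.868 and 0.016), Mx1 (-2.257 and 0.259), Cd8a (-0.123 and 0.015), Cpt1a (-0.243 and 0.071), Gzmb (0.033 and -0.077), Plin2 (0.259 and -0.233) and Ppara (-0.495 and 0.075).

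Rhob, Klf11 and Plin2 passed with the PPARβ agonist, in at least 1 fit, and with neither other agonist against DMSO, but the direct differences of Klf11 (2.12 from the PPARα agonist, -2.19 for PPARγ against PPARβ) passed in neither fit (adjusted p = 0.942 and 0.749 without the block, 0.0680 and 0.0533 with it). Low precision could hide a change of the same size with the other agonists. With the culture sets paired by the block, their highest upper 95% bound was 40.1 percent of the PPARβ agonist's lower bound (Klf11). For Plin2 it was 23.8 percent. A change of the same size thus lay outside the bounds of that fit. The genes were picked by their PPARβ change in these same arrays, which widens such a gap, so low precision is not excluded. Without the block, which leaves the difference between sets in the spread, the share reached 106 percent for Plin2 and 58.7 percent for Klf11, and smaller changes with the other agonists stay open in both fits. More B cells, myeloid cells or dendritic cells would raise their markers, but the 15 tested markers had a median change of -0.056 (bootstrap interval -0.128 to 0.097), although H2-Ab1 alone stood at 1.05. Action of the agonist through its own receptor, the biological explanation that the groups give, was not tested, because no array lacked the receptor.

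The interferon response list stood higher with the PPARβ agonist than with the other 2 agonists. A chance arrangement of the treatments within the culture sets remains undecided, since the real arrangement of the PPARβ label among the 3 agonists ranked 1 of 9 (exact p = 0.111) and 9 arrangements can give no lower p. More B cells, myeloid cells or dendritic cells would raise their markers. The median difference of these markers was -0.020 (bootstrap interval -0.131 to 0.199), against 0.482 for the list, although H2-Ab1 alone stood at 0.923. CD4 T cell markers differed by a mean of -0.14 from the PPARα agonist and by 0.34 for PPARγ against PPARβ. A change in CD4 T cells was not tested and stays open. More interferon gamma transcript with the PPARβ agonist was tested as another explanation. Ifng was highest with that agonist in only 1 of 2 culture sets, set 2. In set 1 it stood at 12.80 with the PPARγ and 12.12 with the PPARβ agonist. The list stood at 9.855 and 10.905 there. Ifng was 3.73 higher in set 1 than in set 2, and the list only 0.127 on average. These values argue against the Ifng level alone setting the list mean. A part played by Ifng stays undecided, since in set 2 the list was also highest with the PPARβ agonist. No other biological explanation was tested.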

How the results depend on the processing

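Alternatives with the block combined with another list test were added only after the results were seen. Of 105 results for named genes, 1908 of 1964 values under the alternatives kept their sign, and 0 of the other 56 belonged to a call. Rhob, Klf11 and Plin2 gave 7 results past a threshold over the comparisons, whose 129 values all kept their sign. In both counts many signs could not change. The block, an intensity trend, another filter or leaving out an array of a group not compared does not alter a fold change. For 5 lists, with 11 such results, 163 of 231 values kept sign and call and the others lost the call. Of these others 4 means changed sign, 2 of the interferon response list for the PPARβ agonist against DMSO (-0.045 and -0.061) and 2 of cholesterol synthesis between the PPARγ and PPARβ agonists (0.064 and 0.038). Where no construction is named below, the cause was not tested. The number of arrays limits these results: with 1 left out, fewer arrays estimate the spread, and the culture sets no longer balance.

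With culture set as a replicate block, limma called 3 genes for the PPARβ agonist against DMSO, 2 against the PPARα agonist, 2 for the PPARγ against the PPARβ agonist and 2 in the test of any agonist, where the fit without it called 1 each. Camera passed 8 lists between the PPARβ and PPARα agonists and 7 between the PPARγ and PPARβ agonists with the block, against 3 and 4. The block changed no other call over all genes tested or of a whole list, while more genes passed adjusted over the list alone with it. With the block and no filter these 4 gene counts were each 2, and with the block, an intensity trend and robust variances they were 10, 11, 11 and 15, with 2 for the PPARγ agonist against DMSO. With the filter at the 60th percentile, which leaves Rhob out, they were 0, and with only the 4 arrays compared, which leaves fewer degrees of freedom, 0 for the PPARβ agonist against DMSO and against the PPARα agonist. Leaving out 1 array gave 0 to 1, 0 to 0, 0 to 2 and 0 to 1.

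Camera with an estimated correlation passed 0 lists in every comparison, as did fry and both with the block. At its preset correlation and with the filter at the 60th percentile, camera passed 0 lists for the PPARα agonist against DMSO, against 1 in the main setting. It then passed 5 between the PPARβ and PPARα agonists, 7 between PPARγ and PPARβ and 1 between PPARγ and PPARα, against 3, 4 and 0. With no filter, camera at the preset correlation passed 2 between the PPARγ and PPARβ agonists. The counts that follow also use the preset correlation. Leaving out 1 array gave 1 to 6 lists for the PPARα, 2 to 7 for the PPARβ and 1 to 6 for the PPARγ agonist against DMSO, 3 to 8 for PPARβ against PPARα, 0 to 5 for PPARγ against PPARα and 4 to 8 for PPARγ against PPARβ. Cholesterol synthesis between the PPARγ and PPARβ agonists turned from -0.173 to 0.064 without PPARβ set 1 and ranged from -0.410 to 0.064 with 1 array left out.

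Adjusted p of Rhob ranged over the alternatives from 1.09e-05 to 0.347 against DMSO. The covariances of changes (PPARα and PPARβ, PPARα and PPARγ, PPARβ and PPARγ) were 0.0285, 0.0290 and 0.0287 with no filter and 0.0141, 0.0160 and 0.0138 at the 60th percentile. They were 0.0401, 0.0469 and 0.0467 in set 1, 0.0452, 0.0412 and 0.0391 in set 2, larger by construction since single arrays are subtracted, and 0.0016, 0.0030 and 0.0011 across sets, where no DMSO array is shared.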

Other observations

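The comparison of the culture sets, its genes and its test were chosen only after the results were seen. Ifng, the cytokine gene of cytotoxic T cells, was higher in culture set 1 (11.83 ± 0.83, n = 4 arrays) than in set 2 (8.10 ± 0.53), a difference of 3.73 (SE 0.385, limma adjusted p = 2.65e-04). The chemokine gene Ccl3 (2.62), the early response gene Egr1 (2.58) and Nfkbid (2.46), a regulator of NF-kB, were also higher in set 1, while the glycolytic gene Aldoc (-2.19), the metallothionein gene Mt1 (-2.10) and the NK receptor gene Klrk1 (-1.95) were lower. limma called 2484 of 12713 genes, 1395 higher and 1089 lower in set 1, and 2150 with a treatment term in the fit. Each set carries 1 prefix, so these p-values measure the spread between arrays within the sets. They do not measure how culture sets vary in general.

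The genes of MYC and ribosome biogenesis, which serve growth, were higher in set 1 by a mean of 0.92, and 25 of 28 passed over all genes tested and 26 adjusted over the list alone (camera adjusted p = 1.87e-22; adjusted p = 0.0086 with an estimated correlation). Activation and costimulation genes were higher by 0.83 (camera adjusted p = 1.36e-10; adjusted p = 0.0933 with an estimated correlation), G2 and M phase genes lower, at -0.29 (3.36e-07; adjusted p = 0.0933 with an estimated correlation), and glycolysis genes lower, at -0.48 (3.44e-07; adjusted p = 0.221 with an estimated correlation). Camera passed 11 lists at its preset correlation and 1 with an estimated correlation, and fry passed 15.

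The real split ranked 1 of 35 splits into 4 and 4, with 2484 genes against at most 0 in any other, which makes a random division unlikely. The other splits mix the sets and so leave the set difference in their spread, and 35 splits allow no stronger rank. No biological explanation was tested, because the labels do not say what the prefix marks.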
